A study of Mus musculus with 24 samples.

How the data were processed

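Gene expression was measured by poly(A) RNA sequencing in 24 libraries of sorted CD4+ T cells from C57BL/6 mice, 3 for each of 8 groups given by age, sex and subset. The deposited values are raw counts of reads per gene, in whole numbers, for 24062 gene symbols. Per the submitters' processing notes, reads were checked with FastQC 0.11.2, trimmed with Trimmomatic 0.35 and aligned to the mouse genome mm10 with TopHat2 2.1.0. Per the same notes they were handled with SAMtools 1.3 and counted with featureCounts 1.5.0-p3, and Subread 2.0.1 is named beside it. The gene annotation, the use of strand and the treatment of reads with several alignments are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart. All 24 value columns were mapped to a sample, and 0 were left unmapped.

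Gene symbols were matched to the GENCODE M21 annotation of the same build for coordinates, exon lengths and chromosomes: 22758 matched a current symbol, 916 an older one, and 388 matched none. Total counts per library, in units of 1e6, were 7.86 to 13.6. Counting intervals and floors (3 counts over a group) cover counting error only, since reads without molecular identifiers are not independent molecules.

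Genes were kept by the filterByExpr rule of edgeR 4.0.16 (minimum count 10, minimum total 15, smallest group 3), which left 11407 of the 15837 genes with any count. Library sizes were scaled by TMM, and edgeR's quasi-likelihood test with robust dispersion was fitted to all 24 libraries with 8 group means and 16 residual degrees of freedom, so that the groups shared an estimate of the spread. Adjusted p-values are those of this test with Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05, wherever no other test is named. The age effect is old minus young, the sex effect male minus female and the subset effect memory minus naive, each averaged with equal weight over the strata it spans. The age by subset, age by sex and sex by subset tests compare these effects. Errors of log2 fold changes are standard errors, and CPM values are means with SD over libraries. For genes with 1 to 3 counts in a group, the ratio of normalised counts is given with an exact 95% counting interval. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used. Principal components were taken from log2 CPM with a prior count of 2.

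The tests, covariates, gene lists, rule for naming genes and most alternatives were fixed before the data were examined. The rule names, per comparison, the 8 largest changes in each direction among called genes with a mean of at least 5 CPM on the higher side and the same sign in each stratum, up to 4 called members of each list, and the 5 smallest p-values in each direction of an interaction, and a fixed set of genes that check labels and purity. Immunoglobulin and T cell receptor variable segments were counted but not named, genes on sex chromosome lists were named apart in sex comparisons, and not every gene the rule allows is printed. The 34 lists, written from general knowledge, hold naive and quiescence, effector memory and homing, Th1, Th2, Th17, follicular helper, regulatory T cell, inhibitory receptor, cytotoxic effector, and cytokine genes. They also hold T cell receptor signalling, type I interferon response, immediate early, heat shock, cell cycle, senescence associated, cholesterol synthesis, glycolysis, oxidative phosphorylation, cytosolic ribosomal protein, mitochondrially encoded, autophagy and lysosome, proteasome, Y-linked, X escape, X-linked immune, sex hormone receptor, B cell, plasma cell, myeloid, CD8 T cell, NK cell, gamma delta T cell, and erythroid and platelet genes. Some genes are on several lists. The result of the sex hormone receptor list and those of some genes under the rule are not reported here. The 26 lists with at least 5 tested members were compared with all other genes by camera (limma) with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which tests a list by itself.

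Samples share replicate numbers across groups, but no label says that a number marks an animal, a day or a batch. By the labels the mice numbered 3 were older than the others in young males (8 against 7 weeks), old males (86 against 83) and young females (11 against 10). The comparisons therefore have no block, and the numbers were not taken as pairs.

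The procedure was tested on counts simulated from the real means and library sizes with 200 genes changed. Genes were drawn independently with the same mean in all libraries otherwise. The rates of false calls thus do not cover differences between libraries such as those described below. For age in naive cells (11135 genes) it recovered 30.4%, 71.2% and 91.0% of genes changed 1.5-fold, 2-fold and 4-fold, and 3.13% of calls were false. For age in memory cells (11163 genes) these values were 20.3%, 74.2%, 86.4% and 7.14%, for age in male naive cells (11142 genes) 17.9%, 49.2%, 81.2% and 3.92%, and for sex in naive cells (11129 genes) 36.4%, 83.6%, 91.2% and 1.44%. For age by sex in naive cells (11155 genes) they were 0%, 7.94%, 66.2% and 2.04%, for age by subset (11151 genes) 18.2%, 52.4%, 88.6% and 5.31%, and for subset (11166 genes) 62.9%, 85.2%, 100% and 6.36%. Of 26 lists, the 1 that was raised was the 1 past the threshold, and a slope of 0.3 on log2 length put into 1 library came back as 0.284, against 0.287 after centring on all libraries. Since the simulated genes were independent, this does not test the preset correlation of camera.

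The alternatives chosen beforehand were DESeq2's size factors, no filter, a stricter filter, non-robust dispersion, DESeq2's Wald test, limma-voom, the compared groups alone, a replicate block, each library left out in turn, genes on sex chromosome lists left out, and other sets of genes for the agreement of the sexes. Alternatives chosen after seeing the data were the removal of each library's smooth trend with exon length (loess, span 0.3, 11335 tested genes with a length), leaving out Rn45s, a ribosomal RNA gene, and Lars2, a tRNA synthetase gene, 3 libraries, 4 male libraries or 8 male libraries, a block within sex, and weeks of age within a group as a term (1 for the males and 1 for the young females numbered 3). In males the term for weeks parts library 3 from libraries 1 and 2, so weeks cannot be told from anything else that sets those libraries apart. Other splits of the libraries were drawn up to 40 times per result to keep the number of refits down.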

Results

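The transcriptome of sorted mouse CD4+ T cells was measured by poly(A) RNA sequencing in 24 libraries, so that age, sex and T cell subset could be compared within a single design. Cells from pooled lymph nodes and spleen of C57BL/6 mice, a common inbred strain, were sorted by surface markers into naive cells, which lack CD44, and effector memory cells, which carry it. Both gates required CD3 and CD4 and excluded CD25. The 8 groups combined young or old age, male or female sex, and naive or effector memory subset, with 3 biological replicates each per the series description. Young males were 7 to 8 weeks old and young females 10 to 11 weeks. Old males were 83 to 86 weeks and old females 85 weeks. In young males, old males and young females the mice numbered 3 were the older ones of their group. Sex and weeks of age thus cannot be fully told apart in the young mice. Total counts per library, in units of 1e6, ran from 7.86 in old male naive 3 to 13.6 in young female memory 1, with a median of 10.6. Of the 24062 genes listed, 11407 had enough counts to be tested. Replicates of a group differed by more than sampling noise in each pair (chi-square per degree of freedom 7.21 to 334), so no library was counted as a duplicate.

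The sex and the subset on the labels matched the genes that report on them in all 24 libraries. The female-specific noncoding RNA Xist (chromosome X, 103460366 to 103483254, mm10) stood at 48.5 ± 10.7 CPM in female naive cells and 0.104 ± 0.134 CPM in male naive cells (SD, n = 6 each). The Y-linked RNA helicase gene Ddx3y (chromosome Y, 1260771 to 1286629) stood at 89.5 ± 14 CPM in male and 0.112 ± 0.130 CPM in female naive cells. Cd44, which encodes the adhesion receptor used in the sort (chromosome 2, 102811141 to 102901665), was 11.0-fold higher in memory cells. Cd4 and Cd3e, which encode parts of the gated receptor complex, stood at 796 ± 187 and 557 ± 78.5 CPM in memory cells and at 681 ± 77.9 and 477 ± 54.3 CPM in naive cells (SD, n = 12 each). In a principal component analysis the first component held 57.6% of the variance and the second 11.5%. The first separated all 12 naive from all 12 memory libraries.

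**Figure D1:**
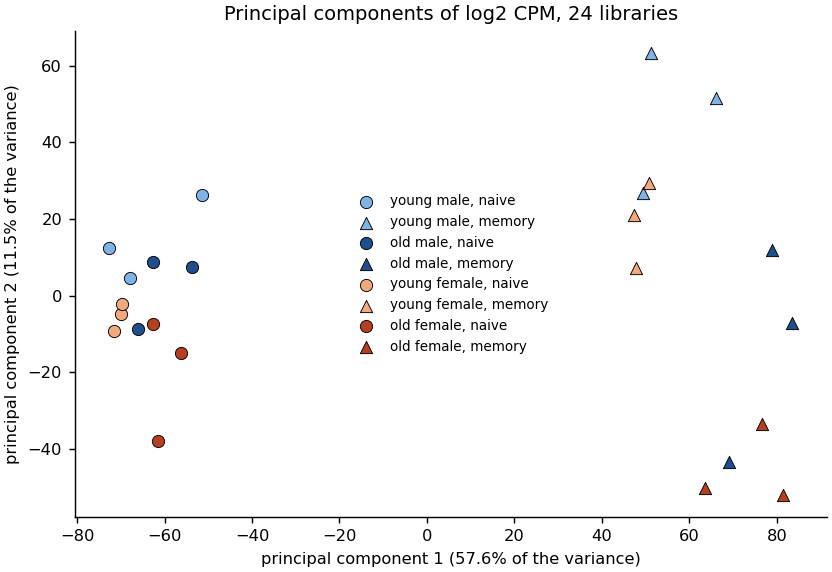
Principal component scores of the 24 libraries from log2 CPM, with the first component (57.6% of the variance) on the horizontal axis and the second (11.5%) on the vertical axis; each point is 1 library, coloured by group. The 12 naive libraries lie on the negative side of the first component and the 12 memory libraries on the positive side.

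Markers of cells that the gates should exclude were uneven across libraries. Cd74, the invariant chain of MHC class II that B cells and antigen-presenting cells express strongly, stood at 482, 228 and 12.3 CPM in young male memory libraries 1, 2 and 3. It stood at 244, 249 and 65.4 CPM in the old male ones. Across the 6 female memory libraries it ran from 12.1 to 73.3 CPM. Mpeg1, a pore-forming protein of macrophages, stood at 467 CPM in young male memory 1 and 91.3 CPM in young male memory 2, against 2.64 CPM in young male memory 3. In old male memory libraries 1, 2 and 3 it stood at 34.2, 39.7 and 0.472 CPM. Foxp3 and Il2ra, the lineage factor and high-affinity cytokine receptor chain of regulatory T cells, reached 32.3 and 51.0 CPM in young male naive 1. They reached 16.1 and 22.8 CPM in old male naive 1. Foxp3 also ranged from 31.0 to 207 CPM within the old male memory group. In old male naive 3 the ribosomal RNA precursor gene Rn45s took 24.9% of all counts, and ribosomal protein genes took 33.7% in old female naive 2 and 28.6% in old female memory 3.

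**Figure D2:**
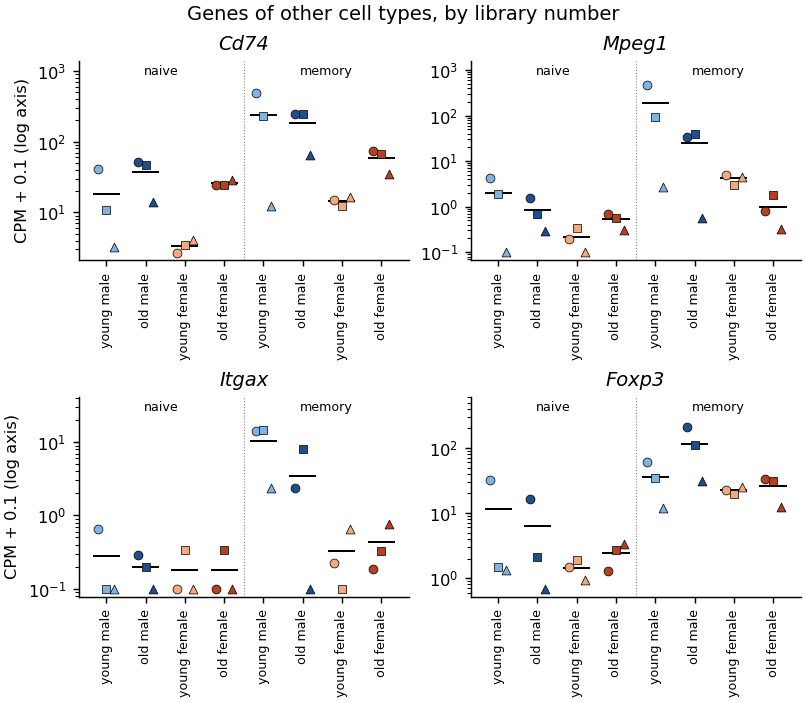
CPM plus 0.1 on a log axis for Cd74, Mpeg1, Itgax and Foxp3 in each library, by group; circles, squares and triangles are libraries 1, 2 and 3 and bars are group means. Cd74 reaches 482 CPM in young male memory 1 and stays at or below 73.3 CPM in the female memory libraries.

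Memory and naive cells differed at many genes. The chemokine receptor gene Cxcr3 rose 427-fold, from 1.52 ± 1.12 to 551 ± 98.2 CPM (SD, n = 12 each; log2 fold change 8.74 ± 0.15, SE, adjusted p = 3.89e-23). Tbx21, the transcription factor that directs Th1 cells, rose 321-fold to 98.8 ± 57.3 CPM. Ccl5, a chemokine of effector cells, rose 198-fold to 470.2 ± 165 CPM. Among genes nearly silent in naive cells, Ttc39c had 5516 counts in memory and 3 in naive libraries, a ratio of 1572 (95% counting interval 538 to 7626). Ascl2, a transcription factor of follicular helper cells, had a ratio of 2005 (359.5 to 79236), and the cytokine gene Il4 a ratio of 912 (163 to 36038). In the other direction Igfbp4, an insulin-like growth factor binding protein, fell 78.7-fold from 2021 ± 603 to 25.2 ± 11.8 CPM. Ampd1, an AMP deaminase, fell 86.0-fold. Dntt, the terminal transferase of receptor rearrangement, fell 39.7-fold, and the homing receptor gene Ccr7 fell 6.52-fold.

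In the quasi-likelihood test of edgeR, 6051 of the 11407 genes differed between the subsets, 3238 higher and 2813 lower in memory cells, 2252 of them by more than 2-fold. All 10 tested Th1 genes were higher in memory cells (median log2 6.24, camera adjusted p = 1.12e-08), as were all 7 Th2 genes (5.82, 7.85e-07) and all 8 Th17 genes (4.09, 4.74e-07). Also higher were all 14 follicular helper genes (2.48, 1.37e-12), all 15 inhibitory receptor genes (3.30, 1.79e-08) and 10 of 12 cytokine genes (3.98, 6.38e-06). Of 25 effector memory and homing genes 22 were higher and 1 lower (4.44, 9.43e-15). Of 18 cytotoxic effector genes 16 were higher and 1 lower (4.61, 3.32e-08). Of 14 senescence associated genes 10 were higher and 2 lower (1.71, 0.00249). Of 22 naive and quiescence genes, such as Lef1 (5.67-fold lower), 19 were lower and 2 higher (-1.37, 1.85e-10). These 10 lists also passed with an estimated correlation, at adjusted p from 0.00373 for Th1 to 0.0432 for senescence.

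Another 6 lists passed with the preset correlation alone. They were the regulatory T cell genes (15 of 16 higher, 1 lower, median log2 3.37, adjusted p = 7.09e-08, and adjusted p = 0.129 with an estimated correlation) and 5 others. The cell cycle genes followed (18 of 24 higher, 1 lower, 2.09, 6.38e-06, and adjusted p = 0.0979 with an estimated correlation), as did the glycolysis genes (10 of 18 higher, 2 lower, 0.37, 0.0249, and adjusted p = 0.254 with an estimated correlation). The cholesterol synthesis genes were lower in 16 of 20 (-0.66, 1.87e-06, and adjusted p = 0.139 with an estimated correlation). Of 72 cytosolic ribosomal protein genes, 68 were lower in memory cells (-0.70, 1.54e-15, and adjusted p = 0.303 with an estimated correlation), Rpl5 by 2.27-fold. Of 15 myeloid genes 12 were higher and 1 lower (4.41, 0.00139, and adjusted p = 0.303 with an estimated correlation). The complement gene C1qa had no count in any naive library and was at least 58.1-fold higher in memory cells, against a floor of 3 counts over the group. Its call was lost without male libraries 1 and 2 of every group (adjusted p = 1.00), an alternative chosen after seeing the data.

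The remaining lists did not pass between the subsets. They were the T cell receptor signalling (8 higher and 5 lower of 22, adjusted p = 0.431), type I interferon response (6 and 9 of 29, 0.257), and immediate early genes (9 and 2 of 19, 0.147). Others were the heat shock (3 and 3 of 14, 0.777), oxidative phosphorylation (8 and 9 of 55, 0.548), autophagy and lysosome (10 and 2 of 19, 0.0627), proteasome (0 and 0 of 26, 0.406), X escape (1 and 4 of 11, 0.406), X-linked immune (7 and 4 of 20, 0.392) and B cell genes (6 and 0 of 11, 0.257). Lists with under 5 tested members had no camera test. All 4 tested plasma cell and all 3 NK cell genes were higher in memory cells, as was 1 of 4 Y-linked genes (Uty). Lower was 1 of 2 CD8 T cell genes (Cd8b1), and the 1 tested erythroid and platelet gene did not pass. None of the 13 mitochondrially encoded genes was in the table, and of 8 gamma delta T cell genes 2 were, with too few counts to be tested. Adjusted over the list alone, the counts were the same for all lists but 4: glycolysis (11 higher, 3 lower), oxidative phosphorylation (5 and 7), ribosomal protein (69 lower) and Y-linked genes (none). The Uty call did not hold without any of 8 single libraries (adjusted p up to 0.0886) or under 6 other alternatives (0.0522 to 0.139), 3 of them chosen after seeing the data. Among the latter was leaving out male libraries 1 and 2 of every group (Uty 0.0898), where 3962 genes were called.

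In naive cells a small set of genes differed with age, several of them by large factors. Rab4a, a small GTPase of endosome recycling (chromosome 8, 123805985 to 123835287), fell 18.5-fold from 10.7 ± 1.46 CPM in young to 0.592 ± 0.209 CPM in old mice (SD, n = 6 each; log2 fold change -4.21 ± 0.27, SE, adjusted p = 4.69e-10). Wdfy1, an adaptor of endosomal Toll-like receptor signalling (chromosome 1, 79702262 to 79776143), fell 8.44-fold (-3.08 ± 0.21, adjusted p = 9.76e-10). Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase (chromosome 13, 119335448 to 119408997), fell 2.40-fold from 55.5 ± 4.60 to 23.1 ± 2.68 CPM. The long intergenic RNA 5830416I19Rik (chromosome 5, 64044978 to 64050228) rose 59.6-fold from 0.148 ± 0.169 to 8.14 ± 1.70 CPM. The BMP receptor gene Bmpr1a (chromosome 14, 34410734 to 34503341) rose 11.5-fold. The inflammatory caspase genes Casp1 and Casp4, neighbours on chromosome 9, rose 9.73-fold and 11.3-fold.

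Gzmk, a granule protease, had 274 counts in old and 3 in young naive libraries, a ratio of 108 (95% counting interval 36.6 to 528, adjusted p = 0.0219). This call was lost without young male naive 2 or old male naive 3 (adjusted p up to 0.0997), with limma-voom (0.139), without male libraries 1 and 2 (0.0515) and without 3 libraries named above for their ribosomal RNA or ribosomal protein counts (0.191). The chemokine gene Ccl5 rose 16.6-fold to 14.7 ± 15.5 CPM, and the inhibitory receptor gene Lag3 (chromosome 6, 124904361 to 124911705) rose 6.78-fold to 5.48 ± 4.05 CPM. The follicular homing receptor gene Cxcr5 rose 4.39-fold, and Cst7, a protease inhibitor of cytotoxic granules, rose 2.35-fold. Apol10b, of the apolipoprotein L family, rose 16.1-fold. The transcribed pseudogene Gm7609 rose 11.0-fold, where reads shared with related copies leave the level uncertain. Besides the genes above, Camk2b, a calcium-dependent kinase, fell 5.25-fold, and the tetraspanin gene Tspan9 fell 4.36-fold. The Ccl5, Lag3 and Cxcr5 calls were lost with limma-voom (0.0636, 0.0671 and 0.0656). Those of Lag3 (0.428), Cxcr5 (0.172), Cst7 (0.304) and Tspan9 (0.0790) were lost without male libraries 1 and 2. Cd86, a costimulatory ligand, fell 3.05-fold from 7.36 ± 1.81 to 2.41 ± 0.625 CPM. In all, 116 genes passed in edgeR's test, 90 higher and 26 lower in old mice, 68 of them by more than 2-fold. The count was 69 without young male naive 2, 65 without old male naive 1, and 72, 76 and 71 without young female naive 1, 2 and 3. The count was 212 with DESeq2 and 76 with limma-voom. Under alternatives chosen after seeing the data it was 77 without the 3 libraries that stood apart in ribosomal RNA or ribosomal protein counts, 68 without the 4 male libraries numbered 1 and 25 without male libraries 1 and 2.

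**Figure D3:**
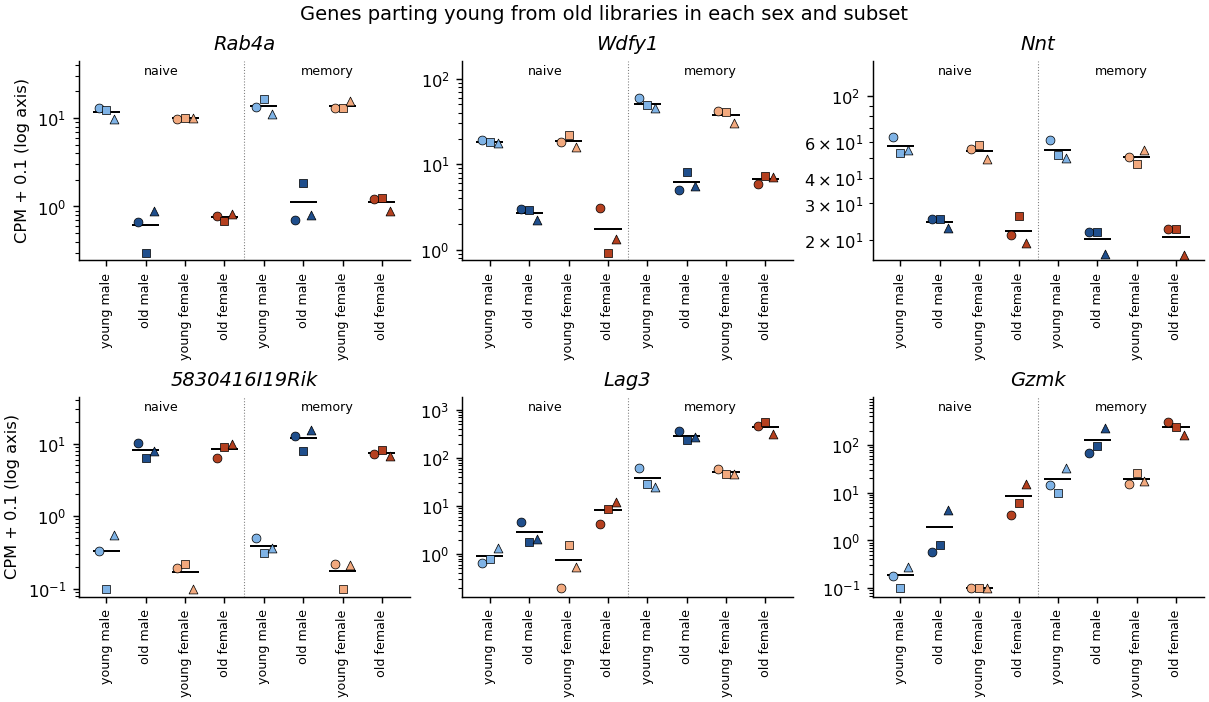
CPM plus 0.1 on a log axis for Rab4a, Wdfy1, Nnt, 5830416I19Rik, Lag3 and Gzmk in each of the 24 libraries, by group; circles, squares and triangles are libraries 1, 2 and 3 and bars are group means. In naive cells Rab4a averages 10.7 ± 1.46 CPM in young and 0.592 ± 0.209 CPM in old mice, and Nnt 55.5 ± 4.60 and 23.1 ± 2.68 CPM.

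Among the gene lists in naive cells, 13 shifted up and 1 shifted down with age under camera's preset correlation, and none of the 14 passed with an estimated correlation. Few single genes carried the shifts. Of 18 cytotoxic genes 3 rose (median log2 0.58, adjusted p = 4.90e-04, and adjusted p = 0.196 with an estimated correlation). Adjusted over the list alone, 5 were higher and 2 lower. Of 15 inhibitory receptor genes 1 rose and 5 did so adjusted over the list alone (0.53, 1.16e-04, and adjusted p = 0.185 with an estimated correlation). Of 10 Th1 genes 2 rose, and 3 adjusted over the list alone (0.60, 0.00142, and adjusted p = 0.185 with an estimated correlation). The calls of the Th1 genes Cxcr3 and Il12rb1 were lost with limma-voom (adjusted p = 0.248 and 0.101). They were also lost with only the groups compared in the fit (0.0718 and 0.0670). Among 14 follicular helper genes 1 rose by either adjustment (0.35, 1.76e-04, and adjusted p = 0.283 with an estimated correlation). Of 20 cholesterol synthesis genes 1 rose, and 2 adjusted over the list alone (0.27, 8.89e-07, and adjusted p = 0.283 with an estimated correlation). No single gene passed among 29 type I interferon response genes, which shifted down (-0.28, 1.34e-04, and adjusted p = 0.283 with an estimated correlation), though 3 were lower adjusted over the list alone.

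The lists of small housekeeping complexes shifted up in naive cells of old mice without any single gene passing, also adjusted over the list alone. The 72 ribosomal protein genes had a median log2 of 0.32 (adjusted p = 1.76e-13, and adjusted p = 0.485 with an estimated correlation). The 55 oxidative phosphorylation genes stood at 0.30 (2.70e-12, and adjusted p = 0.391 with an estimated correlation) and the 26 proteasome genes 0.21 (4.24e-06, and adjusted p = 0.391 with an estimated correlation). Ribosomal protein genes took 33.7% of counts in old female naive 2, the highest share of the 24 libraries. The 25 effector memory genes shifted up (0.21, 0.00221, and adjusted p = 0.283 with an estimated correlation), with 2 higher and, adjusted over the list alone, 6 higher and 1 lower. That shift was lost without old female naive 3 (0.0813). The 16 regulatory T cell genes shifted up with none called by either adjustment (0.29, 0.00484, and adjusted p = 0.503 with an estimated correlation). This call was lost without young male naive 3 (0.105), old male naive 1 (0.103) or old female naive 3 (0.0531). The 18 glycolysis genes shifted up with 1 called by either adjustment (0.14, 0.00676, and adjusted p = 0.283 with an estimated correlation), lost without old female naive 2 (0.0503) or without the 3 libraries (0.141). The 11 B cell genes (1.1, 0.0490, and adjusted p = 0.695 with an estimated correlation) lost their call without young male naive 3 (0.567), old male naive 1 (0.137) or 2 (0.312), young female naive 1 (0.0739), or old female naive 1 (0.0789) or 3 (0.106), and with DESeq2's size factors (0.0519) or the length trend removed (0.0838). The 14 senescence associated genes, 2 higher and 3 adjusted over the list alone (0.52, 0.0426, and adjusted p = 0.283 with an estimated correlation), kept theirs only without young male naive 3, old male naive 1 or young female naive 2. Without any other library the value was 0.0503 to 0.160. It was 0.0713 without a filter and 0.0513 with the stricter one. Among alternatives chosen after seeing the data it was 0.248 with the length trend removed, 0.165 without the 3 libraries and 0.0569 with weeks of age within a group as a term. The other 12 lists did not pass (adjusted p 0.0770 to 0.710).

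In effector memory cells many genes differed with age. Il21, the cytokine by which follicular helper cells act on B cells (chromosome 3, 37222759 to 37232636), rose 9.81-fold from 16.2 ± 6.24 to 159.7 ± 74.6 CPM (SD, n = 6 each; log2 fold change 3.29 ± 0.20, SE, adjusted p = 1.22e-10). Spp1, the secreted phosphoprotein osteopontin (chromosome 5, 104435118 to 104441050), rose 37.8-fold to 119 ± 58.9 CPM (5.24 ± 0.36, adjusted p = 1.30e-09). The inhibitory receptor genes Lag3, Tigit and Pdcd1 (chromosome 1, 94038305 to 94052553) rose 8.18-fold, 5.56-fold and 3.97-fold. Zbtb16, the transcription factor of innate-like T cells (chromosome 9, 48654297 to 48836222), fell 36-fold from 20.9 ± 6.26 to 0.554 ± 0.458 CPM (-5.17 ± 0.42, adjusted p = 4.14e-08). Klrb1c, a receptor of NK and NKT cells (chromosome 6, 128778485 to 128789215), fell 11.2-fold from 257 ± 109 to 23.0 ± 8.65 CPM. Tbx21 fell 3.39-fold, from 152 ± 17.5 to 46 ± 15.3 CPM.

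Among genes past the floor of 5 CPM in the naming rule, the largest increases besides that of Spp1 were those of Iglon5, a cell adhesion molecule (108-fold), the peptidase gene Ecel1 (90.3-fold), and the aspartyl protease gene Bace2 (78.5-fold). Then came 5830416I19Rik (56.2-fold), the actin-severing protein gene Scin (33.4-fold), the interferon-induced membrane protein gene Ifitm2 (30.3-fold) and the sodium and calcium exchanger gene Slc24a3 (27.4-fold). Ifitm2 stood at 1770.4 CPM in old female memory 3 alone. The Ifitm2 call was lost with limma-voom (0.0683) and without male libraries 1 and 2 (0.143). Large decreases besides that of Zbtb16 were those of the RNA-binding protein gene Rbm24 (47.9-fold) and the water channel gene Aqp9 (18.0-fold). Others were those of the cytokine receptor gene Il17rb (16.8-fold), the gut homing receptor gene Ccr9 (16.0-fold), the NK receptor gene Klrc1 (15.9-fold) and the growth factor gene Igf2 (14.9-fold). By edgeR's test 3003 genes differed, 1519 higher and 1484 lower in old mice, 977 of them by more than 2-fold. Without male libraries 1 and 2, an alternative chosen after seeing the data, 1293 were called.

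**Figure D4:**
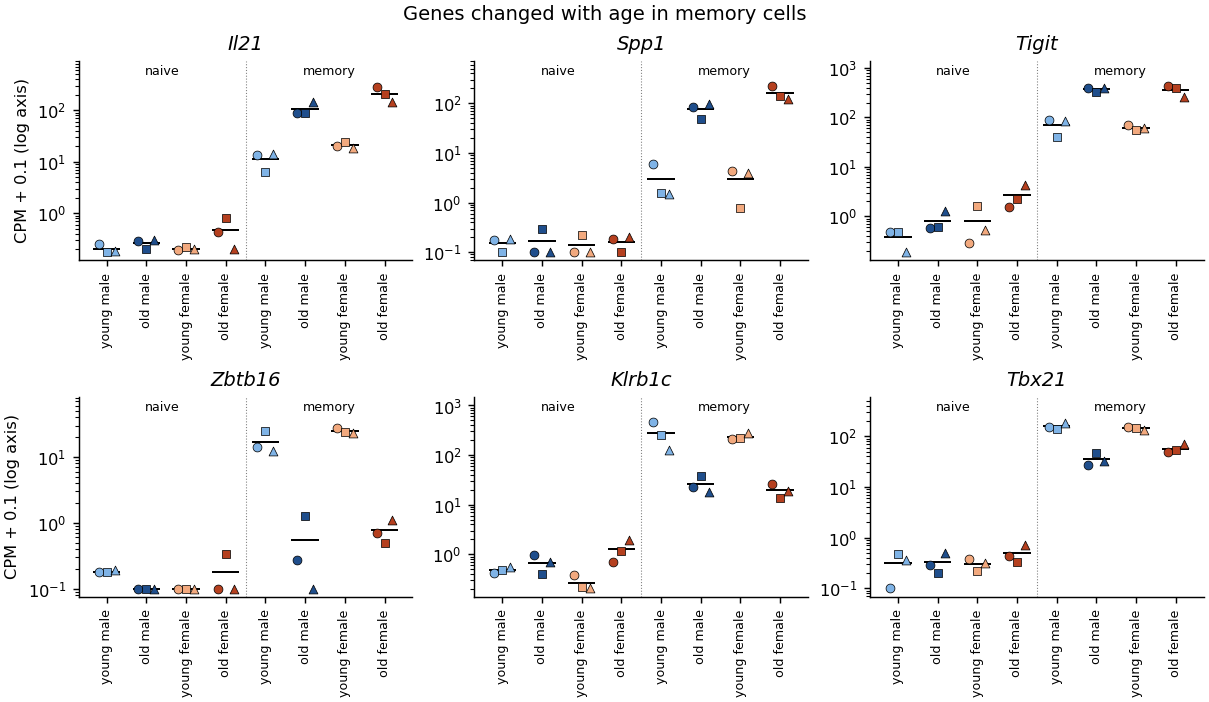
CPM plus 0.1 on a log axis for Il21, Spp1, Tigit, Zbtb16, Klrb1c and Tbx21 in each library, by group; circles, squares and triangles are libraries 1, 2 and 3 and bars are group means. In memory cells Zbtb16 averages 20.9 ± 6.26 CPM in young and 0.554 ± 0.458 CPM in old mice, and Tigit 66.2 ± 18.0 and 367 ± 64.5 CPM.

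Of 14 follicular helper genes, 12 rose with age in memory cells and 13 did so adjusted over the list alone (median log2 1.27, camera adjusted p = 8.35e-11, and adjusted p = 0.0532 with an estimated correlation). Ascl2 was up 12.3-fold and Pou2af1, a transcriptional coactivator, up 4.51-fold. Of 16 regulatory T cell genes 12 rose, and as many adjusted over the list alone (1.16, 3.51e-05, and adjusted p = 0.379 with an estimated correlation). Foxp3 itself did not pass (28.9 ± 17 CPM in young and 70.8 ± 74.8 CPM in old mice). Of 15 inhibitory receptor genes 10 rose and 1 fell, and as many adjusted over the list alone (1.16, 2.54e-05, and adjusted p = 0.0532 with an estimated correlation). Of 14 senescence associated genes 9 rose and 1 fell, and 10 and 1 adjusted over the list alone (0.93, 1.66e-04, and adjusted p = 0.0532 with an estimated correlation). Cdkn2b, a cyclin-dependent kinase inhibitor, rose 7.82-fold. Of 29 type I interferon response genes 21 fell, and 22 adjusted over the list alone (-0.70, 2.57e-10, and adjusted p = 0.0532 with an estimated correlation). The synthetase-like gene Oasl1 fell by 4.38-fold and Rtp4 by 2.50-fold. Of 10 Th1 genes 6 fell by either adjustment, 6 adjusted over the list alone (-0.91, 1.80e-04, and adjusted p = 0.0532 with an estimated correlation). The cytokine receptor gene Il12rb2 fell by 6.75-fold. Of 3 tested NK cell genes, too few for camera, 2 fell and 3 did so adjusted over the list alone (median log2 -2.46). Of 24 cell cycle genes 15 fell, and 18 adjusted over the list alone (-0.91, 2.54e-05, and adjusted p = 0.176 with an estimated correlation). The DNA topoisomerase gene Top2a fell by 3.08-fold. Of 22 naive and quiescence genes 10 fell by either adjustment, 10 adjusted over the list alone (-0.37, 1.08e-04, and adjusted p = 0.176 with an estimated correlation). The chromatin organiser gene Satb1 fell by 4.13-fold.

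Metabolic and housekeeping lists also shifted up in old memory cells. Of 72 ribosomal protein genes 18 rose, and 55 adjusted over the list alone (median log2 0.46, adjusted p = 1.93e-08, and adjusted p = 0.663 with an estimated correlation). Of 55 oxidative phosphorylation genes 17 rose, and 27 adjusted over the list alone (0.37, 1.08e-05, and adjusted p = 0.663 with an estimated correlation). Ribosomal protein genes took 28.6% of counts in old female memory 3. Of 26 proteasome genes 5 rose, and 1 adjusted over the list alone (0.25, 0.00953, and adjusted p = 0.663 with an estimated correlation). This shift was lost without young male memory 2 (0.0533) and with the trend with transcript length removed (0.206), an alternative chosen after seeing the data. Of 18 glycolysis genes 7 rose and 2 fell, 11 and 2 adjusted over the list alone (0.27, 0.0300, and adjusted p = 0.379 with an estimated correlation). The shift was lost without young male memory 1 (0.0602) or young female memory 3 (0.0553), the 4 male libraries numbered 1 (0.103) or male libraries 1 and 2 (0.130), the last 2 also chosen after seeing the data. Of 15 myeloid genes 2 fell, and none adjusted over the list alone (-1.24, 0.0432, and adjusted p = 0.663 with an estimated correlation). That call was lost without young male memory 1 (0.222) or 2 (0.0811), old male memory 3 (0.149), young female memory 1 (0.0535) or 3 (0.0857), or old female memory 2 (0.0553), without the 4 male libraries numbered 1 (0.0878), and with the stricter filter (0.445). The cytotoxic genes split, 6 rising and 6 falling of 18 (6 and 8 adjusted over the list alone, adjusted p = 0.968). Cst7 rose 3.41-fold and Crtam 3.73-fold, while the death ligand gene Fasl fell 3.83-fold. The effector memory genes split in the same way, 5 rising and 6 falling of 25 by either adjustment (0.522). The calcium-binding protein gene S100a6 rose 3.12-fold (a call lost without male libraries 1 and 2, 0.0588) and the chemokine receptor gene Cxcr6 fell 6.23-fold. The other 11 lists tested did not pass (adjusted p 0.131 to 0.960).

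**Figure D5:**
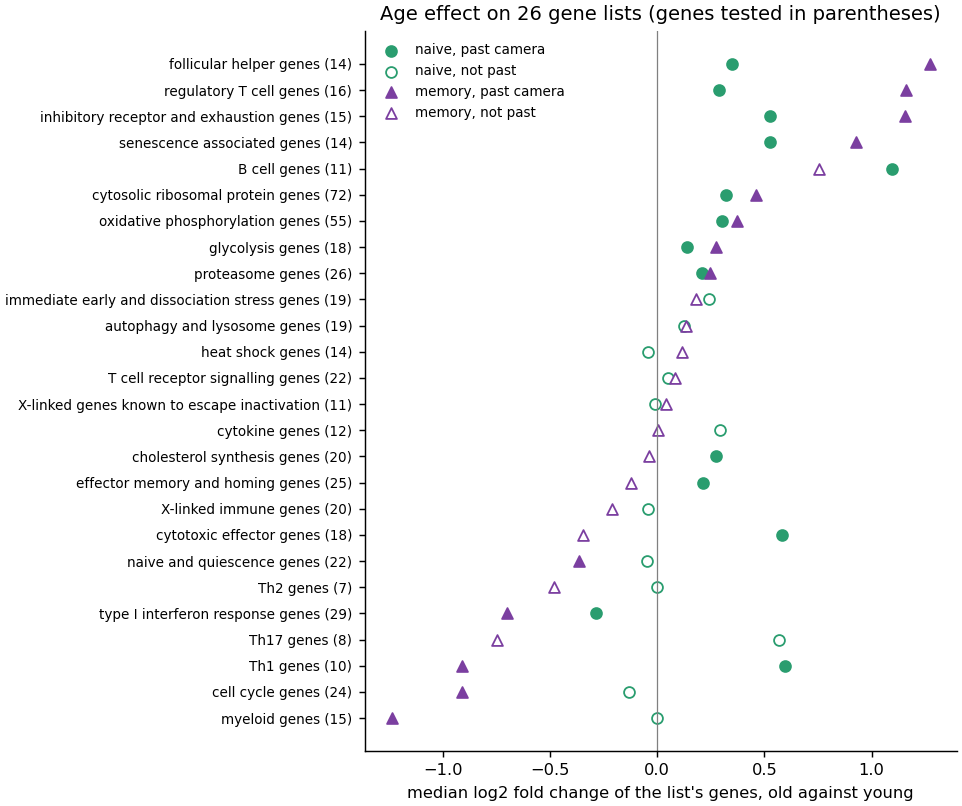
Median log2 fold change with age of the 26 tested gene lists in naive and in memory cells, old minus young, with 1 point per list and subset. The follicular helper genes lie at 0.35 in naive and 1.27 in memory cells, and the Th1 genes at 0.60 and -0.91.

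The age effect differed between the subsets at 502 genes, 219 with a more positive and 283 with a more negative effect in memory cells, 300 of them by more than 2-fold. Ckb, the brain-type creatine kinase, had an age effect 8.14-fold lower in memory than in naive cells (log2 difference -3.03 ± 0.27, SE, adjusted p = 5.71e-07). The phospholipid flippase gene Atp8a2 and Aqp9 followed (-4.57 ± 0.48 and -4.49 ± 0.49, adjusted p = 6.10e-06 and 1.27e-05). On the other side Padi4, an enzyme that converts arginine to citrulline, had a log2 difference of 4.22 ± 0.53 and the prion protein gene Prnp one of 1.84 ± 0.21 (adjusted p = 3.08e-05 and 1.63e-05). The Prnp call was lost without male libraries 1 and 2 (0.0608). The age effects of the subsets shared genes as well: 52 genes were higher with age in both, against 12 for independent lists (Fisher's exact test, one-sided, p = 2.78e-23). In both 21 were lower, against 3.38 (the same exact test, p = 7.58e-15), where genes are not independent replicates. The naive and memory libraries may also come from the same mice, which this test does not take into account. Th1 genes, which shifted up in naive and down in memory cells, passed the test of that difference (median log2 -1.73, adjusted p = 1.98e-08, and adjusted p = 0.00340 with an estimated correlation). The naive side is weaker: Cxcr3 had a low level there, and the naive Cxcr3 and Il12rb1 calls were lost with limma-voom (0.248 and 0.101). Whether the naive shift arose in the naive cells themselves was not tested. Of the 3 NK cell genes 1, Klrb1c, had a lower age effect in memory cells by either adjustment, where the other genes had few or no counts in naive cells. The set tests of the difference were chosen after seeing the data. Without male libraries 1 and 2, 71 genes were called, and without the 4 male libraries numbered 1, 268. Both alternatives were chosen after seeing the data.

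Within each sex the age effect ran in the same direction for nearly all called genes. In naive cells 20 genes passed in males (14 higher, 6 lower) and 68 in females (50 higher, 18 lower). Of the 71 called in either sex 68 had the same sign in both (95.8%, Pearson's r across genes 0.81, with genes not independent). Rab4a, Wdfy1 and 5830416I19Rik were among the genes whose pooled effect above kept its sign in both sexes, which the naming rule required of them. In memory cells 1047 genes passed in males (572 higher, 475 lower) and 1637 in females (854 higher, 783 lower). Of 1986 called in either, 1897 had the same sign (95.5%, r = 0.80). These values are over genes chosen for being called. Across all genes tested the same-sign share was 59.3% (r = 0.177) in naive and 75.6% (r = 0.668) in memory cells. No gene passed the age by sex test of edgeR in naive cells (444 at an unadjusted p under 0.05; 1 with DESeq2 and 0 with limma-voom) or in memory cells (533; 8 with DESeq2 and 0 with limma-voom). In memory cells 2 passed without young male memory 2, 8 without old female memory 1 and 1 without old female memory 2. The male naive count was 45 with DESeq2, 13 with limma-voom and 74 with only the groups compared in the fit. The female naive count was 145 with DESeq2 and 35 with limma-voom. With only the groups compared, 577 passed in male and 926 in female memory cells. Under alternatives chosen after seeing the data, the male counts were 10 in naive and 358 in memory cells without the 4 male libraries numbered 1, and 5 and 98 without male libraries 1 and 2. The female naive count was 41 without the 3 libraries. Among single libraries, the female naive count was 34, 32 and 27 without young female naive 1, 2 and 3 and 35 without old female naive 2. The male memory count was 629 without young male memory 2 and 575 and 693 without old male memory 1 and 3. The female memory count was 717 and 834 without young female memory 1 and 2 and 759 without old female memory 1.

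Between the sexes, the largest differences among the called genes of naive cells were those of sex chromosome genes. Eif2s3y, Ddx3y, Kdm5d and Uty, all Y-linked, were 908-fold, 821-fold, 475-fold and 767-fold higher in males, and Xist was 957-fold lower (-9.90 ± 0.41, SE, n = 6 each; adjusted p = 9.18e-14). These folds average the log2 effects of the young and the old mice and rest on 5 to 8 counts in the other sex, and those of Xist and Uty exceed the ratios of the group means. Of 18 further genes 15 were higher and 3 lower in males. All 18 lie on autosomes but Erdr1, which has no position in the reference and is known as a pseudoautosomal gene (fell by 1.55 on the log2 scale). The Erdr1 call was lost without any of 7 single libraries (adjusted p up to 0.0935). Pde2a, a phosphodiesterase of cyclic nucleotides, stood at 41.4 ± 10.9 CPM in females and 85.4 ± 12.1 CPM in males (1.08 ± 0.13, adjusted p = 4.29e-05). Naip2, an inflammasome sensor, was 2.38-fold higher in males (1.25 ± 0.18, adjusted p = 5.94e-04). The ubiquitin ligase gene Dtx4 was 2.24-fold and the phosphodiesterase gene Pde8a 2.15-fold higher in males. These calls were lost without old male naive 1 or young female naive 1 (adjusted p up to 0.0804 for both). The Dtx4 call was also lost with limma-voom (0.0964) and that of Pde8a without the 3 libraries (0.0822). Without the 4 male libraries numbered 1 the Dtx4 (0.212), Pde8a (0.115) and Erdr1 (0.212) calls were lost. They (1.00, 0.778 and 1.00) and that of Naip2 (0.0807) were lost without male libraries 1 and 2. These alternatives that leave out several libraries were chosen after seeing the data. In all 23 genes passed in edgeR's test, 19 higher and 4 lower in males, against 2271 at an unadjusted p under 0.05. The count rose to 256 without old female naive 1. It fell to 12 without young male naive 1, 9 and 13 without old male naive 1 and 2, 9 and 11 without young female naive 1 and 2, and 13 without old female naive 2. It was 279 with DESeq2 and 680 with the 12 naive libraries alone in the fit. In males the term for weeks of age within a group, chosen after seeing the data, parts library 3 from libraries 1 and 2. With it the count was 115, the 23 among them. It was 15 without the 3 libraries and 8 without the 4 male libraries numbered 1 or without male libraries 1 and 2. Without genes of the sex chromosome lists it was 10.

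The lists that passed between the sexes in naive cells were mostly lower in males, and none of the 7 passed with an estimated correlation. Oxidative phosphorylation genes had a median log2 of -0.36 (adjusted p = 7.66e-15, and adjusted p = 0.641 with an estimated correlation). None was called over all genes, and 32 of 55 were lower adjusted over the list alone. Proteasome genes stood at -0.30 (1.61e-07, and adjusted p = 0.641 with an estimated correlation), with 0 called and 1 lower adjusted over the list alone. Ribosomal protein genes stood at -0.25 (4.72e-07, and adjusted p = 0.846 with an estimated correlation), with 0 called by either adjustment. The ribosomal protein shift was lost without male libraries 1 and 2 (0.0601) and with the trend with transcript length removed (0.419), alternatives chosen after seeing the data. The immediate early shift was lost under the same alternatives (0.525 and 0.168). Of the type I interferon genes Oas1a alone passed, and 7 of 29 were lower adjusted over the list alone (-0.29, 0.00316, and adjusted p = 0.641 with an estimated correlation). Immediate early genes had none called and, adjusted over the list alone, 1 higher and 4 lower (-0.27, 0.0112, and adjusted p = 0.641 with an estimated correlation). The X escape genes had Xist called, and 2 lower adjusted over the list alone (-0.22, 0.0112, and adjusted p = 0.641 with an estimated correlation). The X escape call was lost without young male naive 3 (0.0506), old male naive 3 (0.0581) or old female naive 1 (0.119). B cell genes were higher in males (3.40, 3.95e-04, and adjusted p = 0.641 with an estimated correlation), with none called over all genes and 11 of 11 adjusted over the list alone. Without male libraries 1 and 2, an alternative chosen after seeing the data, their direction turned (0.00190). The other 19 lists did not pass (adjusted p 0.11 to 0.801). The 1 tested erythroid and platelet gene was higher in males (8.07) adjusted over the list alone, and no CD8 T cell or plasma cell gene passed. For a list of 1 gene this adjustment leaves the p-value as it was. In edgeR's test 2271 of the 11407 genes had an unadjusted p under 0.05 in this comparison. The Oas1a call was lost without any of 9 single libraries (adjusted p up to 0.176) and under 6 other alternatives (0.0574 to 1.00).

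In memory cells the sex difference again held the 4 Y-linked genes and Xist, which was 936-fold lower in males. It also held Eif2s3x, an X-linked translation factor that escapes inactivation, at 245 ± 16.6 CPM in males and 389 ± 28.3 CPM in females (SD, n = 6 each; log2 fold change -0.67 ± 0.09, SE, adjusted p = 9.24e-05). The Eif2s3x call was lost without male libraries 1 and 2 (0.470). Mpeg1 stood at 106 ± 179.9 CPM in males against 2.46 ± 1.93 CPM in females. The dendritic cell integrin gene Itgax stood at 6.83 ± 6.32 against 0.278 ± 0.274 CPM, and Pld4, a nuclease of plasmacytoid dendritic cells, at 21 ± 34.8 against 0.567 ± 0.554 CPM. The Mpeg1 mean rested on male libraries 1 and 2. Mpeg1 stood at 467 and 91.3 CPM in young male memory 1 and 2 and at 34.2 and 39.7 CPM in old male memory 1 and 2. It stood at 2.64 and 0.472 CPM in young and old male memory 3, and at up to 4.86 CPM in females. Without male libraries 1 and 2, an alternative chosen after seeing the data, all 3 turned direction (log2 fold changes of -0.76 for Mpeg1, -0.66 for Itgax and -0.89 for Pld4). That fit holds 1 male library per group, at low levels, so it does not show these genes to be lower in males. Itgax reached 2.29 CPM in a male memory library numbered 3, against at most 0.672 CPM in female memory libraries. Il21 was 1.92-fold lower in males (-0.94 ± 0.18, adjusted p = 0.0224). This call was lost without old male memory 1 or 2, young female memory 2 or old female memory 1 (adjusted p up to 0.106), with the memory libraries alone in the fit (0.168), without the 4 male libraries numbered 1 (0.196) and without male libraries 1 and 2 (1.00). In all 40 genes passed, 31 higher and 9 lower in males. Of these 34 were not on a sex chromosome, and 2480 genes were at an unadjusted p under 0.05. Single libraries moved this count. It was 12 and 260 without young male memory 1 and 3 and 10, 11 and 602 without old male memory 1, 2 and 3. It was 21, 13 and 12 without young female memory 1, 2 and 3, and 8, 327 and 25 without old female memory 1, 2 and 3. It was 269 with DESeq2, 20 with limma-voom, 26 without a filter, 19 without genes of the sex chromosome lists and 6 with the 12 memory libraries alone in the fit. The term for weeks of age within a group, an alternative chosen after seeing the data, parts male library 3 from male libraries 1 and 2. It thus cannot tell weeks from what else sets those libraries apart. With it the count was 128, with 38 of the 40 among them. Under others so chosen it was 64 with the length trend removed, 25 without the 3 libraries, 6 without the 4 male libraries numbered 1 and 10 without male libraries 1 and 2. The 15 named genes not on a sex chromosome each lost their call without at least 4 libraries, Mpeg1 without 8 (adjusted p up to 0.139). Under the other alternatives the calls of Mpeg1, Itgax and Pld4 were lost in 7, 5 and 6.

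Among the lists, B cell and myeloid genes were higher in male memory cells. Of 11 B cell genes none passed over all genes and 9 were higher adjusted over the list alone (median log2 3.64, or 3.34 with Fcer2a at its bound; adjusted p = 3.55e-04, and adjusted p = 0.531 with an estimated correlation). Of 15 myeloid genes 1 passed and 11 were higher adjusted over the list alone (1.92, 8.61e-04, and adjusted p = 0.531 with an estimated correlation). Th17 genes had none called and 3 of 8 higher adjusted over the list alone (0.50, 0.00458, and adjusted p = 0.531 with an estimated correlation). Lower in males were ribosomal protein (-0.44, 9.52e-18, and adjusted p = 0.531 with an estimated correlation) and oxidative phosphorylation genes (-0.36, 1.70e-13, and adjusted p = 0.531 with an estimated correlation). Proteasome genes were lower as well (-0.26, 7.55e-06, and adjusted p = 0.531 with an estimated correlation). None of these 3 lists had a called gene, also adjusted over the list alone. Also lower were immediate early genes (-0.21, 8.61e-04, and adjusted p = 0.531 with an estimated correlation), with 0 called and 3 adjusted over the list alone. Follicular helper genes were lower (-0.21, 0.00577, and adjusted p = 0.531 with an estimated correlation), with 1 called and 3 adjusted over the list alone. X escape genes were lower (-0.36, 7.90e-05, and adjusted p = 0.0728 with an estimated correlation), with 2 of 11 called and 4 adjusted over the list alone. The other 17 lists did not pass (adjusted p 0.0541 to 0.925). Of the lists too small for camera, both CD8 T cell genes (median log2 3.69), 2 of 4 plasma cell genes (1.57) and the 1 erythroid and platelet gene (8.54) were higher in males adjusted over the list alone, and none over all genes. For the list of 1 gene this adjustment leaves the p-value as it was. In edgeR's test 2480 of the 11407 genes had an unadjusted p under 0.05 in this comparison. The follicular helper call was lost without old female memory 1 (0.0701), and the Th17 call without a filter (0.0875) and with the stricter one (0.0609). When male libraries 1 and 2 were left out, an alternative chosen after seeing the data, the ribosomal (0.524), oxidative phosphorylation (0.122), proteasome (0.517), follicular helper (0.524), immediate early (0.158), Th17 (0.283) and B cell (0.524, direction turned) calls were lost and the myeloid direction turned (0.0463).

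The sexes were also compared within each age. In young naive cells the 5 genes that passed were Xist and the 4 Y-linked genes. In young memory cells the 7 were these with Eif2s3x and Tcf4, a transcription factor of B cells and plasmacytoid dendritic cells (log2 fold change 4.09, adjusted p = 0.00735), named after its value was seen. In old naive cells 42 genes passed, 36 of them not on a sex chromosome, among them Pde2a (1.42, adjusted p = 0.000198). In old memory cells 18 passed, of which 12 were not. With only the groups compared in the fit the counts were 74 in young naive and 17 in old naive cells, so their order turned with the fit. With weeks of age within a group as a term, chosen after seeing the data, they were 5 and 88, and 26 in young and 36 in old memory cells. With DESeq2 the counts were 169 in old naive, 36 in young memory and 212 in old memory cells, and limma-voom gave 14 in old naive cells. The old memory count was 28 with the stricter filter, 35 with non-robust dispersion and 6 with only the groups compared. Without genes of the sex chromosome lists 0, 13, 1 and 7 passed in young naive, old naive, young memory and old memory cells. Under further alternatives chosen after seeing the data, 10 in old naive and 7 in old memory cells passed without the 3 libraries, 6 and 8 without the 4 male libraries numbered 1, 10 and 9 without male libraries 1 and 2, and 29 in old memory cells with the length trend removed. The old naive count was 7, 16 and 17 without old male naive 1, 2 and 3 and 164, 10 and 19 without old female naive 1, 2 and 3. Leaving out single memory libraries, the old count was 8, 8 and 144 without old male memory 1, 2 and 3 and 64, 457 and 11 without old female memory 1, 2 and 3. The young memory count was 14 and 73 without young male memory 2 and 3. No gene differed in its sex effect between the subsets in edgeR's test (426 at an unadjusted p under 0.05; 9 with DESeq2 and 0 with limma-voom), and 6 did without young male memory 3. Whether the sex effect differed between ages is the age by sex test given above.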

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

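The set tests of the age by subset difference were chosen after the result was seen, as were, among the tests of explanations, those of RNA from other cells for the age genes and for the memory genes over 4-fold, that of a strain variant, that of the male libraries for the third pattern, and the alternatives that leave out male libraries or 3 libraries or remove a length trend. The rule that an explanation counts as excluded or borne out only where a 95% bootstrap interval lies on 1 side of the bound was also added after the values were seen, and it left 2 results undecided that the values alone would have decided.

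The age effect differed between memory and naive cells at 502 genes by edgeR's interaction test. The lists below were singled out by camera with the preset correlation, on the same contrast (medians of memory minus naive age effects, log2). The Th1 list differed by a median of -1.73, the Th17 list by -1.35, and the cytotoxic list by -0.93. Differences were also negative for the type I interferon (-0.60), cell cycle (-0.48), effector memory (-0.47), cholesterol synthesis (-0.39) and naive and quiescence lists (-0.29). The regulatory T cell list differed by 0.87, the follicular helper list by 0.74, the inhibitory receptor list by 0.43 and the senescence list by 0.27. Of these 12 lists, Th1 alone also passed with an estimated correlation (adjusted p = 0.00340, against 0.119 to 0.519 for the other 11). The effector memory call was lost without old female naive 3 (0.0609) or young male memory 3 (0.0664), and the cytotoxic call without any of 12 single libraries (0.0507 to 0.105) or without the 4 male libraries numbered 1 (0.0547). The regulatory T cell call was lost without male libraries 1 and 2 (0.108).

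Among genes named for the age effect in either subset, the difference was -4.04 ± 0.68 for Ccl5 (SE, adjusted p = 0.00129), -2.08 ± 0.45 for Casp1 (0.00782), -2.06 ± 0.51 for Apol10b (0.0185) and -1.89 ± 0.48 for Casp4 (0.0255), all of which rose more in naive cells. It was -4.49 ± 0.49 for Aqp9 (1.27e-05) and -3.63 ± 0.58 for Ccr9 (8.55e-04), which fell in memory cells. The genes with the smallest p-values were Ckb (-3.03 ± 0.27, 5.71e-07), Abi3 (-1.99 ± 0.19, 1.42e-06) and Atp8a2 (-4.57 ± 0.48, 6.10e-06) in the negative direction. In the positive direction they were Prnp (1.84 ± 0.21, 1.63e-05), F2rl1 (1.29 ± 0.16, 2.46e-05), Padi4 (4.22 ± 0.53, 3.08e-05), Gprasp2 (3.42 ± 0.44, 5.14e-05) and Pck2 (1.64 ± 0.22, 5.85e-05). Of 40 splits of the libraries 1, the real one, gave as many genes as 502, and the highest other gave 362. These splits shuffled age within each sex and subset, which removes the age effect from both subsets. They therefore do not test whether the age effects of the subsets differ by chance, and decide nothing on the 502 genes.

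The first pattern weighed was a set of 17 genes, among them Rab4a, Wdfy1, Nnt, 5830416I19Rik, Casp1 and Casp4, whose young and old libraries did not overlap in any of the 4 sex and subset strata and whose age effect was over 2-fold, while 72 genes separated at any size, against 0.143 expected by chance if the 4 strata were independent. If the naive and memory libraries of a sex always separated together, chance would give 57.0. A trend with transcript length was excluded as the whole cause, since 100% of the 17 stayed called in both subsets with the trend removed. RNA of other cells in male libraries 1 and 2 cannot give an age effect in females, and the 17 were chosen for separating in females as well. That choice by itself argues against such RNA as the whole cause for the 17. The median size in females, 2.85, tests nothing further, since a female effect was a condition of the choice. In males the median was 2.35, a ratio of 1.21 (interval 0.909 to 1.72). The genes were chosen to separate the ages in both sexes, so this ratio does not decide whether such RNA added to the male effects. A strain or colony variant that goes with age cannot be told apart from age itself. The labels give 1 strain name, and colonies of C57BL/6 mice are known to differ at Nnt, whose neighbour Gm7120 was also among the 17. Of the 17 genes, 17.6% passed the age by subset test, against 27.9% of 960 other genes over 2-fold in memory cells. The 17 were chosen for changing in both subsets and the 960 by memory cells alone, so this comparison decides nothing. Age remains open beside such a variant as the explanation the design names.

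The second pattern was the set of genes outside the sex chromosomes called between the sexes, Erdr1, without a position in the reference, counted among them. For the 16 genes over 4-fold higher in male memory cells, the median log2 fold change went from 4.81 to -0.71 without male libraries 1 and 2, a ratio of -0.148 (interval -0.223 to 0.234), which is consistent with RNA of other cells in those libraries, with Cd74 at 482 CPM and H2-Aa at 334 CPM in young male memory 1, although the CD3 and CD4 gate would remove such cells. For the other 18 memory genes the ratio was 0.557 (0.407 to 0.723) and for the 18 naive genes 0.846 (0.668 to 1.01), and both stay undecided because the intervals cross a bound set before. A trend with transcript length was excluded as the cause of the median of all 3 sets, with ratios of 0.998 (0.983 to 1.02), 0.967 (0.813 to 1.13) and 0.940 (0.837 to 1.08). With the trend removed 16 of 16, 16 of 18 and 12 of 18 genes stayed called, so it is not excluded for each single gene. The intervals of this pattern cover genes, which share the same libraries, and not the choice of libraries. A difference between the sexes remains open for all 3 sets and was not tested apart from these explanations. The 16 genes were chosen in the fit that holds male libraries 1 and 2. Without those, 1 male library per group is left, which cannot exclude a sex effect on single genes of the 16.

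The third pattern was the shift of the ribosomal protein, oxidative phosphorylation and proteasome lists (153 genes), up with age and down in males in both subsets. With the trend of all other genes with length removed, 55.9% of the age shift (interval 47.8 to 65.0; mean of medians 0.31 before and 0.17 after) and 47.5% of the sex shift (42.7 to 54.0; -0.32 and -0.15) was left. Without old male naive 3, old female naive 2 and old female memory 3, 67.3% (61.2 to 69.5) and 73.6% (71.4 to 77.0) was left. The 47.5% lies under the bound of 50% set before for the trend as the cause, but its interval crosses that bound. The other values lie between the bounds, so neither explanation is excluded or borne out, and part of the shift may come from such differences between libraries. Without male libraries 1 and 2, with 1 male library left per group, 22.2% of the sex shift was left in memory cells (17.8 to 28.2; -0.35 and -0.08) and 64.9% in naive cells (57.9 to 74.8; -0.29 and -0.19). The memory value fits a sex shift carried by those libraries, and the naive value decides nothing. What sets those libraries apart was not tested here, and the intervals cover genes and not the choice of libraries. Age and sex stay open.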

How the results depend on the processing

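The alternatives that remove the length trend, leave out Rn45s and Lars2, leave out 3, 4 or 8 named libraries or block within sex, the term for weeks of age within a group, and the age by subset set tests, were chosen after the result was seen. The cause of a move was not tested. With DESeq2's size factors, and without Rn45s and Lars2, no count of genes moved by over 1.5 times.

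With 1 library left out at a time, the counts of called genes ranged as follows. Age gave 65 to 146 in naive cells and 2097 to 3670 in memory cells. It gave, in male naive cells 15 to 20, in female naive cells 27 to 81, in male memory cells 575 to 1141 and in female memory cells 717 to 2375. Sex gave 9 to 256 in naive cells and 8 to 602 in memory cells. It gave, in young naive cells 5 to 6, in old naive cells 7 to 164, in young memory cells 5 to 73 and in old memory cells 8 to 457. Subset ranged from 5862 to 6292, age by subset from 335 to 647, age by sex from 0 to 0 in naive and 0 to 8 in memory cells, and sex by subset from 0 to 6. Counts of lists ranged from 10 to 14 for age in naive and 11 to 15 in memory cells, 6 to 9 for sex in naive and 9 to 11 in memory cells, 16 to 17 for subset and 11 to 14 for age by subset.

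DESeq2's Wald test called 212 genes for age in naive cells, 45 in male and 145 in female naive cells. It called 279 for sex in naive and 269 in memory cells, 169 in old naive, 36 in young memory and 212 in old memory cells. It called 1 and 8 for age by sex in naive and memory cells, and 9 for sex by subset. The sexes' age effects in naive cells had the same sign in 88.1%. With limma-voom the counts were 76 for age in naive cells, 13 in male and 35 in female naive cells, 20 for sex in memory and 14 in old naive cells. Agreement was 100% same sign and r = 0.915 in naive cells and r = 0.862 in memory cells. Without a filter, sex in memory cells gave 26, age by sex in memory cells 1, and the agreement in memory cells was 96.5% with r = 0.784. The stricter filter gave 28 and non-robust dispersion 35 for sex in old memory cells.

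With only the compared groups in the fit, the counts were 74 for age in male naive cells, 577 in male and 926 in female memory cells. They were 680 for sex in naive and 6 in memory cells, 74 in young naive, 17 in old naive and 6 in old memory cells. Same-sign shares were 87.0% in naive and 96.8% (r = 0.860) in memory cells. Without genes on the sex chromosome lists sex gave 10 in naive and 19 in memory cells, and 0, 13, 1 and 7 in young naive, old naive, young memory and old memory cells. Over all genes tested, the agreement of the sexes was 59.3% with r = 0.177 in naive and 75.6% with r = 0.668 in memory cells. Over genes called by the pooled age result with a mean of at least 5 CPM it was 100% and 99.7% with r = 0.889. The pooled effect is the mean of the male and female effects. Same signs were thus largely fixed by that choice, and these shares decide nothing.

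The labels do not say whether the replicate numbers pair the samples, and the data do not settle it. Deviations of same-numbered naive and memory libraries correlated at -0.41 to 0.50 across genes (log2 CPM of at least 2), over 0.1 in 7 of 12 pairs. Of the naive libraries 7 of 12 correlated best with the memory library of their own number, which is a hint from the data and not the design. With the number as a replicate block, sex gave 69 in naive, 161 in memory, 18 in young memory and 42 in old memory cells, no other count of genes moved by over 1.5 times, and the senescence list lost its call for age in naive cells (0.0542). With the number within age and sex as the block between the subsets, Uty lost its call (0.0739). With the block within sex, sex gave 110 in naive, 125 in memory, 71 in old naive, 30 in young memory and 81 in old memory cells, and r in memory cells was 0.833.

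With weeks of age within a group as a term, sex gave 115 in naive, 128 in memory, 88 in old naive, 26 in young memory and 36 in old memory cells, no other count of genes or lists moved by over 1.5 times, and the calls of all named genes held. In males this term parts library 3 from libraries 1 and 2, so these moves cannot be put down to weeks of age. With the length trend removed, sex gave 64 in memory and 29 in old memory cells. Without the 3 libraries, age gave 77 in naive and 41 in female naive cells. Sex gave 15 in naive, 25 in memory, 10 in old naive and 7 in old memory cells. The agreement in memory cells was 97.7% with r = 0.871. Without the 4 male libraries numbered 1, age gave 68 in naive, 10 in male naive and 358 in male memory cells. Sex gave 8 in naive, 6 in memory, 6 in old naive and 8 in old memory cells. Age by sex in memory cells gave 1, age by subset 268, 11 lists passed for sex in naive cells, and the agreement in memory cells was 97.8% with r = 0.836. Without male libraries 1 and 2, which leaves 1 male library per group whose spread is taken from the other groups, age gave 25 in naive, 1293 in memory, 5 in male naive and 98 in male memory cells. Sex gave 8 in naive, 10 in memory, 10 in old naive and 9 in old memory cells. Subset gave 3962, age by sex 2 and 2, and age by subset 71. For lists, 4 passed for sex in memory cells, r was 0.683 in naive and 0.785 in memory cells. The sex effects of Itgax (-0.66), Mpeg1 (-0.76) and Pld4 (-0.89) in memory cells reversed, which with 1 male library per group does not show lower levels in males.

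With an estimated correlation, camera passed 0 lists for age and for sex in either subset, 10 for subset and 1 for age by subset. With fry, 3 lists passed for age in naive cells, 10 for age in memory cells, 1 for sex in naive and 1 for sex in memory cells. For subset 22 passed with fry, and for age by subset 10. Of the named genes called, all calls held with each library left out for 17 of 26 in age in naive cells, 83 of 105 in age in memory cells, 7 of 16 and 6 of 21 for sex, 117 of 118 for subset and 10 of 10 for age by subset. Under the other alternatives these numbers were 11, 74, 6, 5, 109 and 8. Depth limits genes under about 10 counts in 3 libraries, which were not tested.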

Other observations

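The splits of the libraries were planned, and the counts without genes on the sex chromosome lists were chosen after the result was seen. Up to 40 splits per result were drawn. For age in naive cells 1 of 40 splits, the real one, gave as many genes as 116, and the highest other gave 1. For age in memory cells 1 of 40 gave 3003 and the highest other 603. For subset 1 of 40 gave 6051 and the highest other 0. Chance is excluded for age in both subsets at this number of splits. The cells were sorted into the subsets beforehand, so the subset count was bound to exceed the others and decides nothing. For sex in naive cells 1 of 40 gave 23 and the highest other 0, but genes such as Xist separate the real split of the sexes in advance, so this count excludes nothing by itself. Without the genes on the sex chromosome lists 1 of 40 gave the real 10 and the highest other 0, so chance is excluded for these at this number of splits. For sex in memory cells 2 of 40 splits gave as many as 40 genes and the highest other gave 998, several times the real count, so chance is not excluded and the libraries hold a structure other than sex. Without the genes on the sex chromosome lists 3 of 40 gave as many as 19, and the highest other gave 997. For age by sex and sex by subset the real count was 0, so all 40 splits gave as many, with up to 23 in naive and 910 in memory cells and up to 6 for sex by subset. The 910 again points to a structure of the memory libraries.

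With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest others were 20 and 1 for age in male naive cells, 68 and 0 in female naive cells, 1047 and 1 in male memory cells and 1637 and 906 in female memory cells. For sex, genes on the sex chromosome lists included, they were 5 and 0 in young naive, 42 and 0 in old naive, 7 and 0 in young memory and 18 and 1070 in old memory cells, where 2 of 10 gave as many. The 1070 is several times the real count and points to a structure of the old memory libraries other than sex.

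The share of Rn45s in old male naive 3 was 24.9% of counts, that of Lars2 was 3.53% and the library's TMM factor was 0.645, while old female naive 2 had a factor of 0.769. Ifitm2 stood at 1770.4 CPM in old female memory 3, against 307 ± 717 CPM over the 6 old memory libraries.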
